A study of Homo sapiens with 8 samples.

How the data were processed

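RNA was sequenced from control and TAZ knockdown cells of the CT27 line. Per the labels' protocols, RNA was purified with a spin-column kit, libraries were made with a low-input kit that amplifies full-length cDNA, and paired-end reads of 101 bases were generated. The kit is not described there as marking strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Per the submitters' processing notes, bcl2fastq, Subread 2.0.3, featureCounts, DESeq2 and Picard 2.26.6 were used with the build hg38. The aligner and the annotation version are not given in the sources used here. The deposited count table holds whole-number read counts per gene symbol, not normalized, with 1 column per lane. The deposited comparison table holds values that the authors made with DESeq2, per the file headers: a mean of counts divided by size factors (a signal), a log2 fold change with its standard error and their ratio, and a p-value with an adjusted p-value. Its positive log2 fold changes stand for a higher level in the knockdown. Each of its genes has at least 11 counts in total over the libraries.

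The titles give a library and a lane for each of the 8 samples: control libraries 1 and 3 and knockdown libraries 1 and 3, each on 2 lanes. This was checked with a chi-square test of the counts of each pair of columns over genes with at least 20 counts. Its ratio to the degrees of freedom was 1.11 to 1.19 for 2 lanes of 1 library. It was 1.22 to 1.24 for columns of different control libraries and 65.1 to 65.7 for columns of different knockdown libraries. The lanes were summed. The control libraries differed by slightly more than lanes do, so they were kept as 2 libraries, and a fit with both summed into 1 was added after the data were seen. The 8 columns held 10316746 to 19229281 counts and the summed libraries 20664404 to 38394017. The table has 26485 genes, of which 6099 had no count, and 0 columns were left unused. Some genes named rest on few counts, such as TP63 with 4 in knockdown library 3, and for these counting error adds to the spread between libraries; the intervals and floors given cover counting error only.

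Genes were filtered with filterByExpr at its defaults, which kept 14589, and scaled with TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, on group alone, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05; a second count also asked for an absolute log2 fold change of at least 1. The common biological coefficient of variation was 0.246. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM (counts scaled to library size) use the TMM-scaled library sizes. XIST, TSIX and the Y-linked genes stayed in the tests and counts of genes but were left out of the written gene tables. The change of each knockdown library is its log2 CPM, with a prior count of 2, minus the mean of the control libraries. With 2 libraries per group a permutation test has 3 splits and cannot reach 0.05. No gene or list was tested that way, and the number of genes under each split is given as description only.

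Before the data were examined, 27 gene lists were fixed, covering the Hippo pathway, YAP/TAZ targets, trophoblast states, signalling pathways, the cell cycle, stress, other cell types and RNA quality. Of these, 26 had tested members. The list of mitochondrially encoded genes had 0 members in the table used here. Each list was compared with all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the lists; none of the 10 calls holds with an estimated correlation, which rests on 2 residual degrees of freedom. The percentile of a list's median in a single knockdown library was taken among 10000 random lists matched on mean expression. It describes that library.

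The named genes follow a rule fixed before the data were examined. It takes WWTR1 and YAP1; the 12 largest changes per direction and the 2 largest per list and direction among genes that pass the test; 12 genes of trophoblast state; and the 3 smallest p-values per direction. The second part gave 0 genes, so the 12 largest changes per direction shared by both knockdown libraries, at 10 CPM or more in a group, were added after the data were seen; members named beside a list were also chosen after their values were seen. Gene positions and NCBI gene numbers were taken from a RefSeq table of GRCh38, the same build as hg38. Changes shared by both knockdown libraries were set against the number for independent lists and against 100 simulations of unchanged knockdown libraries.

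The scripts were tested on simulated data with 200 changed genes among 14589. Each gene was drawn with the trend of the spread over these libraries at its expression, alike in both groups. The quasi-likelihood test recovered 2, 16, 44 and 49 of 50 genes changed 1.5-, 2-, 4- and 8-fold, with 3 false calls. In the same simulation DESeq2 recovered 2, 16, 46 and 48 with 8 false calls. Of 20 simulated unshifted lists camera called 0, and it called a list shifted 2-fold (adjusted p = 1.69e-36). Genes were drawn independently of each other there. This says nothing about false calls for lists whose members move together, such as the interferon list (estimated correlation 0.999). Alternatives to scaling, filter, test, unit of replication and replicate block, and the fits without each library in turn, were run, with DESeq2 1.42.0 and limma-voom among them. Figures were drawn with matplotlib 3.10.9.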

Results

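RNA sequencing was carried out on CT27, an established human trophoblast stem cell line from placenta, grown in stem-state culture. Control cells were compared with cells in which TAZ, the transcriptional co-activator encoded by WWTR1 and regulated by the Hippo pathway, had been depleted with a short hairpin RNA. The comparison asks how global gene expression in the stem state changes when TAZ is lost. The series holds 8 samples, 4 per group, and the labels show that each pair of samples is 1 library sequenced on 2 lanes. Counts of the lanes were therefore summed, which left 2 control libraries and 2 TAZ knockdown libraries, numbered 1 and 3 in the labels of each group. Libraries numbered 2 are not among the samples. The sample-sheet numbers in the titles lie close together within each group and far apart between the groups. A difference in processing along that order could not be told apart from the knockdown. The totals were 33348867 and 38394017 counts in control libraries 1 and 3, and 25778566 and 20664404 counts in knockdown libraries 1 and 3. No label says that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

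WWTR1 (NCBI gene 25937, hg38 chromosome 3, 149517235 to 149724788) was about 3-fold lower in both knockdown libraries. Its level was 37.7 and 38.4 CPM (counts scaled to library size) in control libraries 1 and 3, and 13.3 and 11.9 CPM in knockdown libraries 1 and 3, from 1226, 1436, 353 and 252 counts. The group means were 38.0 ± 0.48 CPM (SD, n = 2) and 12.6 ± 0.99 CPM (SD, n = 2). The log2 fold change of knockdown over control was -1.59 (SE 0.12), with an adjusted p of 0.191 by edgeR's quasi-likelihood test over 14589 genes and of 4.02e-12 by DESeq2 on the same 4 libraries. Its paralog YAP1 stood at 550.6 and 565.5 CPM in the controls and at 387.5 and 490.5 CPM in knockdown libraries 1 and 3 (log2 fold change -0.35, SE 0.15), a difference that did not pass the test (edgeR adjusted p = 0.375, DESeq2 adjusted p = 0.488).

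The control libraries were nearly alike and the knockdown libraries were not. Over genes at or above 10 CPM, the median absolute log2 difference was 0.04 between the control libraries and 0.29 between the knockdown libraries. A chi-square test of the summed counts gave a ratio to its degrees of freedom of 1.32 for the control pair, close to the 1.11 to 1.19 of 2 lanes of 1 library, and of 120.9 for the knockdown pair. The first principal component of log2 CPM held 56.5% of the variance and set knockdown library 3 apart, and the second held 40.4% and set knockdown library 1 apart. Against the mean of the controls, 883 genes were at least 2-fold higher and 499 at least 2-fold lower in knockdown library 1. The corresponding numbers for knockdown library 3 were 762 and 1070.

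**Figure D1:**
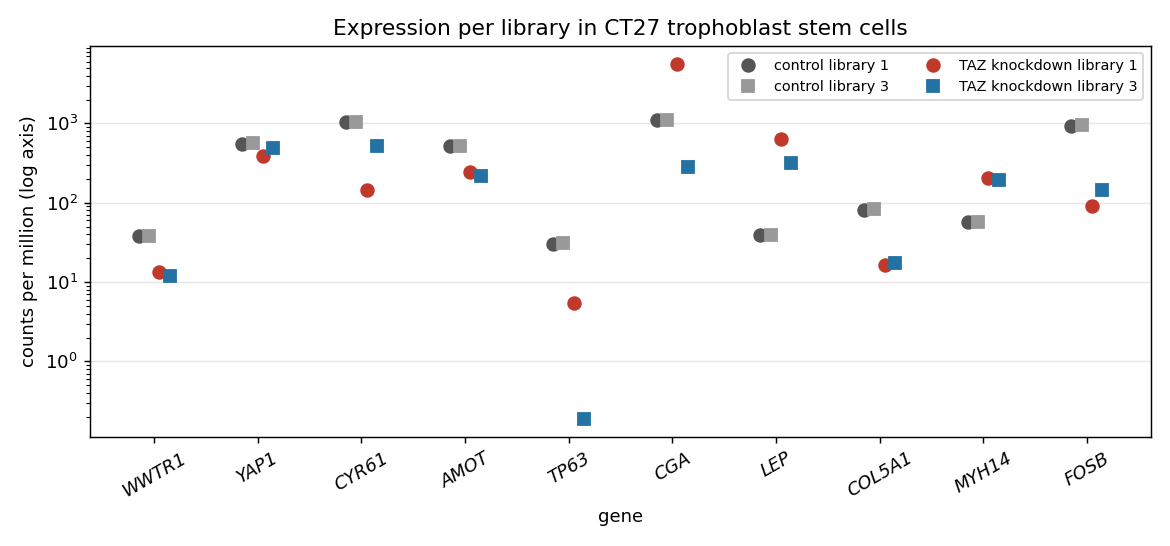
Expression of 10 genes in CPM (log axis) in each of the 4 libraries; each point is 1 library with its lanes summed, circles are libraries 1 and squares libraries 3. The control points overlie each other, and WWTR1 lies at 13.3 and 11.9 CPM in the knockdown libraries against 37.7 and 38.4 CPM in the controls.

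Some genes moved the same way in both knockdown libraries: 316 genes were at least 2-fold higher and 216 at least 2-fold lower in both, and 72 and 78 of these reached 10 CPM on average in a group. Lists of these lengths that were independent of each other would share 46.1 and 36.6 genes, and 100 simulations of unchanged knockdown libraries against the same controls gave means of 7.54 and 22.1 genes. The simulated knockdown libraries had the spread pooled over both groups. That spread includes the nearly alike controls, so the simulated numbers may be too low and the excess over them too large. Across genes, which are not independent replicates, the changes in the 2 knockdown libraries had Pearson's r = 0.33 (simulated 0.06) and a covariance of 0.179 (simulated 0.0108). Splitting the controls would leave 1 library on each side, so they were not split, and part of the excess may come from the shared controls. A further 107 genes were at least 2-fold higher in knockdown library 1 and at least 2-fold lower in library 3, and 15 genes the other way round.

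With the 4 libraries as replicates, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05, and therefore 0 genes at least 2-fold changed. The smallest adjusted p was 0.191, and 2267 genes had an unadjusted p under 0.05. DESeq2 on the same libraries called 627 genes, 270 higher and 357 lower in the knockdown, of which 380 were changed at least 2-fold. edgeR's likelihood ratio test called 568 genes, 299 higher and 269 lower, and limma-voom called 0. Without knockdown library 1 the edgeR test called 9221 genes and without knockdown library 3 it called 8550, because the spread then came from the control libraries alone; without control library 1 or 3 it called 0 (363 and 351 at an unadjusted p under 0.05).

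The smallest p-values with a higher level in the knockdown belonged to MYH14, a non-muscle myosin heavy chain, APOE, a lipid transport protein, and MAN1C1, a Golgi mannosidase. MYH14 was at 57.4 ± 0.68 CPM in controls and 199.4 ± 7.85 CPM in the knockdown (SD, n = 2), a log2 fold change of 1.80 (SE 0.09). APOE went from 43.3 ± 2.85 to 157.8 ± 0.17 CPM (log2 fold change 1.87, SE 0.10) and MAN1C1 from 5.42 ± 0.23 to 27.6 ± 2.3 CPM (2.35, SE 0.14). With a lower level in the knockdown these were COL5A1, a fibrillar collagen chain, PLK2, a polo-like kinase, and PLCXD3. COL5A1 went from 82.8 ± 1.72 to 16.9 ± 0.88 CPM (log2 fold change -2.29, SE 0.11), PLK2 from 354.0 ± 3.22 to 74.4 ± 9.35 CPM (-2.25, SE 0.13), and PLCXD3 from 32.9 ± 1.41 to 8.83 ± 0.10 CPM (-1.90, SE 0.12). All 6 had an adjusted p of 0.191 by edgeR's quasi-likelihood test, and DESeq2 called all 6, with adjusted p-values from 1.88e-31 for COL5A1 to 2.4e-16 for PLCXD3.

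Because no gene passed the edgeR test, the planned rule for the largest changes named no gene, and the 12 largest changes shared by both knockdown libraries in each direction were chosen after their values were seen. On the higher side, MAGEA10, a cancer/testis antigen, went from 3.02 ± 0.42 to 46.1 ± 20.6 CPM (SD, n = 2), MAGEA4 from 18.8 ± 0.10 to 223.2 ± 172.2 CPM, and MAGEA3, MAGEA6 and MAGEA12 had log2 fold changes of 3.81, 3.73 and 3.39. CSAG1 was also higher (log2 fold change 3.40). Other MAGEA genes moved less or in 1 library, MAGEA8 by 0.35 and -0.06 and MAGEA11 by 2.14 and 0.03 on the log2 scale in knockdown libraries 1 and 3. Near-identical copies can split reads, so each level is uncertain. LEP, the hormone leptin, was at 39.6 and 39.7 CPM in the controls and at 641.5 and 319.7 CPM in knockdown libraries 1 and 3. CALN1, NEFM, CYP1B1 and FRAS1 were higher by 4.31, 3.57, 3.21 and 5.21 on the log2 scale, FRAS1 mainly in knockdown library 3 (102.4 CPM, against 6.34 CPM in library 1 and 1.17 and 1.74 CPM in the controls). By DESeq2 all of these except MAGEA8 and MAGEA11 passed, with adjusted p-values from 4.3e-19 for LEP to 0.0257 for FRAS1.

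On the lower side of the same choice stood FOSB and DUSP1, which are induced within minutes of stimulation, KLF2, a transcription factor, and ID1, a target of BMP signalling. FOSB went from 938.2 ± 9.82 to 118.4 ± 39.1 CPM (SD, n = 2), DUSP1 from 169.7 ± 1.52 to 32.2 ± 8.04 CPM, KLF2 from 10.5 ± 0.56 to 1.61 ± 0.34 CPM, and ID1 from 16.7 ± 0.17 to 2.60 ± 1.40 CPM. CDK14, LAYN, SCNN1A and OSR2 had log2 fold changes of -2.68, -2.82, -2.02 and -2.06. ALPPL2 was lower by -2.38 on the log2 scale, with its near-identical copy ALPP leaving its reads uncertain. TP63, the transcription factor that marks cytotrophoblast, was at 30.2 and 31.4 CPM in the controls, at 5.51 CPM in knockdown library 1 and at 0.189 CPM, 4 counts, in library 3. DESeq2 called each of these except TP63 (adjusted p = 0.354), with adjusted p-values from 5.78e-21 for FOSB to 0.00229 for LAYN.

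The genes of the YAP/TAZ target signature fell as a list. Of its 19 tested members 16 were lower in both knockdown libraries, 3 went opposite ways and 0 were higher in both, with a median log2 fold change of -0.79 (camera with a preset correlation of 0.01, adjusted p = 1.17e-06 over 26 lists). The list's call was lost with an estimated correlation (adjusted p = 0.575). Among all tested genes, 29.5% were lower and 30.8% higher in both knockdown libraries. These shares are the background for such counts in this and the other lists. CYR61, a matricellular protein and a standard reporter of YAP and TAZ activity, was at 1035.0 and 1030.4 CPM in the controls and at 146.8 and 517.0 CPM in knockdown libraries 1 and 3. CTGF was at 42.9 and 40.7 CPM against 5.74 and 25.3 CPM, and AMOTL2 at 323.2 and 318.1 CPM against 81.6 and 193.6 CPM. ANKRD1 was near 2 CPM in the controls and parted, with 0.453 CPM in knockdown library 1 and 3.79 CPM in library 3. The test over all genes called 0 members by edgeR and 2 by DESeq2, F3 (DESeq2 adjusted p = 0.0114) and LATS2 (0.0101), both lower; adjusted over the list alone edgeR called 0 and DESeq2 7.

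The list of immediate early and heat shock genes moved with the YAP/TAZ targets: 8 of 15 members were lower and 2 higher in both knockdown libraries (median log2 fold change -0.56, camera adjusted p = 0.00411, adjusted p = 0.699 with an estimated correlation). The list was fixed in advance as a possible sign of how cells were handled, and whether handling differed was not tested. FOS was at 1120.2 and 1110.5 CPM in the controls and at 281.7 and 525.8 CPM in knockdown libraries 1 and 3, while HSPA1A and HSPA1B, near-identical copies, stood at 0.14 and 0.37 log2 units from the controls in library 1 and at -0.25 and -0.30 in library 3. The Hippo pathway list fell too, by a median of -0.22 (adjusted p = 0.00115, adjusted p = 0.575 with an estimated correlation), and shares AMOTL2, LATS2 and PTPN14 with the target list. Of its 26 members 14 were lower and 3 higher in both knockdown libraries. AMOT, a scaffold that binds YAP and TAZ, was at 516.7 and 524.7 CPM against 244.7 and 214.8 CPM, and TEAD1, a DNA-binding partner of TAZ, at 536.2 and 536.9 CPM against 309.3 and 348.3 CPM; DESeq2 called AMOT, TEAD1 and LATS2 (adjusted p = 1.63e-09, 0.00186 and 0.0101). Adjusted over the list alone, edgeR called 3 Hippo and 2 immediate early genes.

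**Figure D2:**
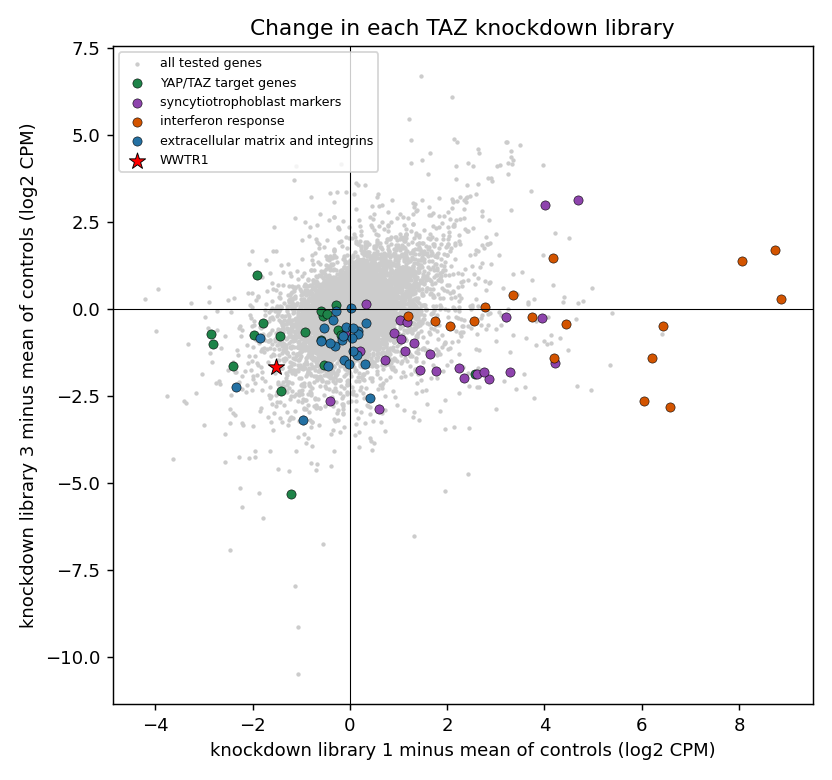
Log2 change in CPM against the mean of the controls, knockdown library 1 on the horizontal axis and knockdown library 3 on the vertical axis; each point is 1 tested gene, with 4 gene lists and WWTR1 coloured. YAP/TAZ targets lie mostly at lower left (16 of 19 lower in both), while interferon-response genes and syncytiotrophoblast markers lie to the right in library 1 and mostly below 0 in library 3.

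Markers of the cytotrophoblast stem state fell as a list, with 18 of 26 tested members lower and 2 higher in both knockdown libraries (median log2 fold change -0.41, camera adjusted p = 2.03e-05, adjusted p = 0.575 with an estimated correlation). DESeq2 called 4 lower members: GATA3, a trophoblast transcription factor (1355 and 1388 CPM in controls, 868.0 and 842.6 CPM in knockdown libraries 1 and 3), NR2F2 (285.9 and 280.0 against 92.7 and 42.7 CPM), PEG10 and FZD5. It called PAGE4 as higher (16.1 and 16.4 against 32.4 and 58.5 CPM). The integrin ITGA6 was at 561.2 ± 3.58 CPM in controls and 354.6 ± 98.9 CPM in the knockdown (SD, n = 2; edgeR adjusted p = 0.309), and E-cadherin (CDH1) at 1904 ± 5.36 and 1701 ± 6.50 CPM (edgeR adjusted p = 0.52). ELF5 was at 9.67 ± 0.63 and 8.01 ± 0.65 CPM (edgeR adjusted p = 0.457). TEAD4 was below the controls in knockdown library 1 (103.9 CPM) and above them in library 3 (187.3 CPM), against 160.7 and 157.1 CPM. Adjusted over the list alone, edgeR called 2 members and DESeq2 10.

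Markers of the syncytiotrophoblast, the fused hormone-producing layer, moved in opposite directions in the knockdown libraries. The list's median log2 change was 1.55 in library 1, with 24 of 26 members higher, and -1.24 in library 3, with 23 of 26 lower; of 10000 random lists matched on expression, 100% and 0% had a lower median. CGA, the common subunit of the glycoprotein hormones, was at 1109.7 and 1114 CPM in the controls, 5658 CPM in knockdown library 1 and 285.3 CPM in library 3. SDC1 was at 146.7 and 144.7 CPM, 457.5 CPM and 60.1 CPM, and CGB5 at 254.5 and 252.6 CPM, 1551 CPM and 69.2 CPM, the last uncertain since CGB copies share reads. LEP and CRH were higher in both knockdown libraries and were the only members called by DESeq2 (adjusted p = 4.3e-19 and 4.74e-05). GCM1, which drives fusion, was at 97.8 and 96.5 CPM in controls and at 112.9 and 41.9 CPM in knockdown libraries 1 and 3. Across groups the list was not called (camera adjusted p = 0.172, adjusted p = 0.806 with an estimated correlation). Without knockdown library 1 it was called as lower (adjusted p = 5.6e-16), and without library 3 as higher (7.26e-118), where the lone library is assumed to vary like the controls; without control library 1 or 3 it was called as higher (0.0104 and 0.0132).

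Extravillous trophoblast markers, of the invasive fate, were not called as a list by camera (median log2 fold change -0.08, adjusted p = 0.199; without knockdown library 1 they were, at 5.43e-06, and without control library 3, at 0.0383), with a median change of 0.20 in knockdown library 1 and -0.54 in library 3. HLA-G was at 12.2 and 10.6 CPM in controls and at 28.6 and 7.90 CPM in knockdown libraries 1 and 3. PLAC8 (38.2 and 40.3 against 7.66 and 11.2 CPM) and SERPINE2 (25.3 and 27.4 against 11.9 and 14.3 CPM) were lower in both and were called by DESeq2 (adjusted p = 1.12e-10 and 0.00122). Cell column markers had a median of -0.16 over 9 members (adjusted p = 0.467), and pluripotency and amnion markers, of which 2 were tested, had a median of 0.99 (adjusted p = 0.24), with DPPA4 called by DESeq2 as higher (adjusted p = 0.00354).

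The list of extracellular matrix and integrin genes fell, with a median log2 fold change of -0.42 and 15 of 25 members lower and 1 higher in both knockdown libraries (camera adjusted p = 1.23e-05, adjusted p = 0.575 with an estimated correlation). Most of the change was in knockdown library 3, where 24 members were lower and the median was -0.89, against 15 members and -0.11 in library 1. Of 10000 random lists matched on expression, 46.1% had a lower median in library 1 and 0% in library 3. The list's median therefore did not stand out in library 1. DESeq2 called COL5A1, the laminin chain LAMA5 (1685 and 1667 CPM in controls, 1119 and 894.7 CPM in knockdown libraries 1 and 3) and THBS1, all lower. Fibronectin (FN1) was at 404.3 and 406.1 CPM in the controls, 208.7 CPM in knockdown library 1 and 44.8 CPM in library 3 (DESeq2 adjusted p = 0.108). The mesenchymal transition list had a median of -0.34 (adjusted p = 0.13) and the mesenchyme list, 7 members, of -0.71 (adjusted p = 0.103). In the latter COL1A2 was at 1378 and 1406 CPM in controls, 668.5 CPM in knockdown library 1 and 0.899 CPM in library 3, while COL1A1 stayed between 125.8 and 158.7 CPM.

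WNT signalling genes were called as lower (median log2 fold change -0.19, camera adjusted p = 0.0134, adjusted p = 0.575 with an estimated correlation), although their mean was 0.07, since a few members were far higher. Of 39 members 19 were lower and 9 higher in both knockdown libraries, and without knockdown library 1 the list was not called (adjusted p = 0.679). DESeq2 called TCF7L1 (61.5 and 57.6 CPM in controls, 16.8 and 8.19 CPM in knockdown libraries 1 and 3), TCF7L2, APC, SFRP1 and FZD5 as lower, and FZD2 as higher. TCF7L1 and TCF7L2 are DNA-binding partners of β-catenin, and SFRP1 and APC restrain the pathway. NOTCH signalling genes were not called as a list by camera (median 0.01, test direction lower, adjusted p = 0.98), with only the ligand DLL4 called by DESeq2, as higher (2.80 and 2.46 against 6.95 and 6.72 CPM). Genes of the TGF-beta and BMP response were not called as a list either (median -0.31, adjusted p = 0.172), with ID1 called by DESeq2; their median was -0.03 in knockdown library 1 and -0.83 in library 3.

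Genes of G2 and mitosis fell as a list, by a median of -0.22 on the log2 scale (camera adjusted p = 0.00509, adjusted p = 0.742 with an estimated correlation). All 20 members were lower in knockdown library 1 and 11 in library 3, and without library 1 the list was not called (adjusted p = 0.819). MKI67, a marker of cycling cells, was at 332.3 ± 0.59 CPM in controls and 247.2 ± 30.9 CPM in the knockdown (SD, n = 2; edgeR adjusted p = 0.275), and CENPF was the only member called by DESeq2 (adjusted p = 0.00308). S phase genes had a median of 0.10 (adjusted p = 0.398), cyclin D and CDK inhibitor genes one of -0.05 although their mean was 0.14 (adjusted p = 0.69), and p53 targets one of 0.24 (adjusted p = 0.152). The integrated stress response (median -0.09, adjusted p = 0.0943), hypoxia genes (median 0.01, test direction lower, adjusted p = 0.398) and sterol synthesis genes (median -0.02, adjusted p = 0.259) were not called as lists by camera. The stress list was called without control library 1 (0.0166), control library 3 (0.0132) or knockdown library 3 (2.66e-17). Within the stress list ATF3 and PPP1R15A were lower in both knockdown libraries, by -2.31 and -1.84 in library 1 and by -1.16 and -1.20 in library 3 on the log2 scale (DESeq2 adjusted p = 0.00308 and 1.88e-05).

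Interferon-response genes rose as a list (median log2 fold change 3.42 over 17 members, camera adjusted p = 0.00332, adjusted p = 0.742 with an estimated correlation), and knockdown library 1 alone accounts for the call. The median change was 4.19 in library 1, with 17 members higher, and -0.34 in library 3, with 6 higher and 11 lower; without library 1 the adjusted p was 0.565 and the direction turned. IFIT1, an antiviral effector, was at 2.06 and 2.81 CPM in the controls, 163.3 CPM in knockdown library 1 and 0.331 CPM in library 3. ISG15 was at 44.2 and 43.8 CPM, 450.4 CPM and 58.7 CPM, and OAS3 at 1.11 and 1.26 CPM, 333.2 CPM and 3.22 CPM. DESeq2 called OAS1, OAS3, IFI27 and USP18. OAS1, OAS3 and USP18 were also above the controls in library 3, by 1.70, 1.40 and 1.47 on the log2 scale. For OAS1 this rests on few reads, with 0.331 CPM there against 0.0923 and 0.0267 CPM in the controls, near the floor.

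Among signs of RNA quality, ribosomal RNA genes set the same library apart. They took 0.229% of the counts in knockdown library 1, against 0.0239% and 0.0222% in control libraries 1 and 3 and 0.0182% in knockdown library 3. Replication-dependent histone transcripts, which lack a poly(A) tail, rose as a list (median log2 fold change 0.90, camera adjusted p = 0.000145, adjusted p = 0.575 with an estimated correlation), with 14 of 21 members higher in both knockdown libraries, but the list was not called without knockdown library 1 (adjusted p = 0.616) or without knockdown library 3 (0.0693). Their share was 0.0112% of counts in knockdown library 1 and 0.0066% in library 3, against 0.00489% and 0.00495% in the controls. Cytosolic ribosomal protein genes fell by a median of -0.10 (adjusted p = 0.00452, adjusted p = 0.751 with an estimated correlation), 73 of 78 lower in library 1 and 38 in library 3, and without library 1 the adjusted p was 0.819. Markers of other placental cells were not called as lists by camera: endothelial (5 members, median -0.36 although their mean was 0.13, adjusted p = 0.541) and macrophage and leukocyte (4 members, median 0.75, adjusted p = 0.179). DESeq2 called CD74 of the latter as higher (adjusted p = 0.0023). The pan-leukocyte gene PTPRC had 0 counts in each of the 4 libraries, which allows up to 3 counts, for counting error only.

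**Figure D3:**
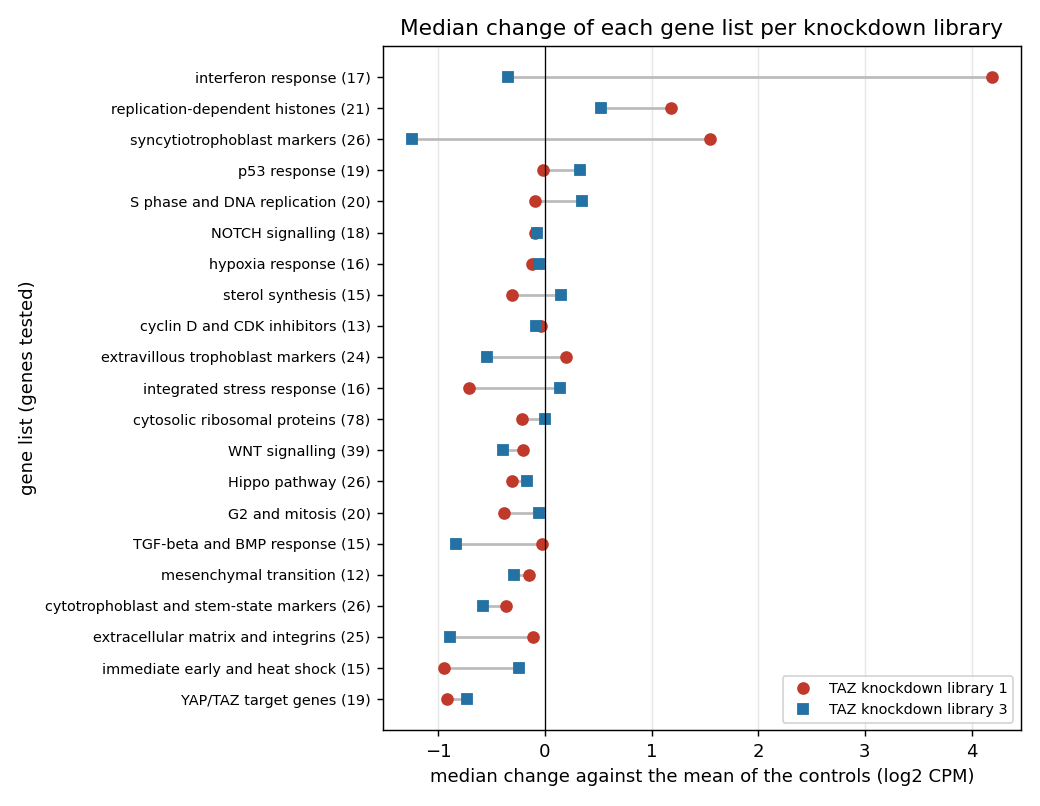
Median log2 change in CPM against the mean of the controls for each gene list with at least 10 tested genes (number tested in brackets), with a circle for knockdown library 1 and a square for library 3. The YAP/TAZ targets lie below 0 in both libraries, whereas the interferon list lies at 4.19 and -0.34 and the syncytiotrophoblast list at 1.55 and -1.24.

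The authors' deposited table of the same comparison lists 16065 genes, with 2114 higher and 2156 lower in the knockdown at an adjusted p under 0.05. A rerun of DESeq2 on the 8 lane columns as separate samples gave log2 fold changes that differ from the authors' deposited table by at most 0.00119, and called 4233 genes, of which 4224 are called there. In the authors' deposited table WWTR1 has a log2 fold change of -1.59 and an adjusted p of 4.16e-62, YAP1 one of -0.35 and 0.00512, and TP63 one of -3.43 and 0.0211. Since the rerun reproduces them, these p-values appear to count lanes of 1 library as replicates. With DESeq2 on the 4 summed libraries the adjusted p was 4.02e-12 for WWTR1, 0.488 for YAP1 and 0.354 for TP63. With edgeR's quasi-likelihood test it was 0.191, 0.375 and 0.336. Of the 627 genes called by DESeq2 on the 4 summed libraries, 627 are also called in the authors' deposited table and 627 have the same direction there. edgeR's quasi-likelihood test on the 4 libraries called 0 genes, so it could share 0 calls only. Its log2 fold changes had Pearson's r = 0.9999 with the deposited ones across 14589 genes, both from the same counts. Of the 4196 genes called in the authors' deposited table that were tested here, 4138 had both knockdown libraries on the same side of the control mean and 58 on opposite sides, 1.38% against 55.2% of the genes not called there. Calls and sides come from the same libraries. A gene with knockdown libraries on opposite sides has a small group difference and a large spread, so it could hardly be called. The contrast therefore does not show that the calls hold in each library.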

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

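The direction of WWTR1 and its size held in all alternatives run. Its log2 fold change was -1.60 with DESeq2 on 4 libraries, -1.59 with edgeR's likelihood ratio test, -1.59 and -1.59 with the 8 columns as separate samples (edgeR and DESeq2) and -1.59 with the title number as a replicate block. It passed the threshold in these 5 and without knockdown library 1 or 3, and ran from -1.68 to -1.52 when 1 library was left out. Of 741 alternative values of the other 39 named genes, 731 kept their direction. DESeq2 on 4 libraries called 26 of these genes. All 26 had been picked from the same libraries, for the smallest p-values or for large changes shared by both knockdown libraries. For these 26 a kept direction was largely built in, so the 731 is no measure of robustness. The others were fixed by name beforehand, were not called by DESeq2, and include the 5 genes with a reversed value. ANKRD1, near 2 CPM, reversed to -0.59 with limma-voom, -0.27 on lane 2 only, -0.36 with the library number and -0.22 with the title number as a replicate block. With 1 library left out the log2 fold change ran from -2.06 to 1.00 for ANKRD1, from -0.62 to 0.23 for TEAD4, from -1.97 to 2.34 for CGA, from -0.53 to 1.32 for HLA-G and from -1.22 to 0.21 for GCM1; the extremes were the fits without a knockdown library.

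The count of called genes, 0 with edgeR's quasi-likelihood test and 2267 at an unadjusted p under 0.05, depended on the test and on the unit of replication. DESeq2 on 4 libraries called 627 (380 at least 2-fold) and edgeR's likelihood ratio test 568 (461). The 8 columns as separate samples gave 3682 (698) with edgeR and 4233 (1016) with DESeq2, which counts lanes as replicates. Other scalings, other filters, limma-voom (2315 at an unadjusted p under 0.05), a single lane and both controls summed, a fit added after the data were seen, gave 0. Leaving out 1 library gave from 0, without either control library, to 9221 genes, without knockdown library 1 (0 to 1899 at least 2-fold). The self-test made calls at this sample size, but each gene's spread there followed its expression alone and was alike in both groups. Here the control libraries were nearly alike and the knockdown libraries were not. The self-test therefore cannot tell whether the low count is a matter of sample size. edgeR's quasi-likelihood test estimates each gene's spread from 2 libraries per group, moderated over genes with 1.94 prior degrees of freedom. The likelihood ratio test leaves that step out and called 568 genes with the same counts and filter. Whether the step also causes the difference from DESeq2 was not tested. The overlap with the authors' deposited table, 0, became 3562 with edgeR and 4224 with DESeq2 on the 8 columns, and 627 with DESeq2 on 4 libraries, the last added later.

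No label says that libraries of the same number in the 2 groups belong together. The differences between libraries 1 and 3 in the 2 groups had r = -0.006 across genes, but the control libraries differ by little more than lanes do, so this cannot show whether the numbers pair them. With the library number as a replicate block edgeR called 0 genes (1537 at an unadjusted p under 0.05), and with the title number as a replicate block on the 8 columns 2116 (522 at least 2-fold). With the library number as a replicate block 17 lists were called, among them extravillous (adjusted p = 0.0387), syncytiotrophoblast (0.0328), TGF-beta and BMP (0.0382), mesenchymal transition (0.0387), integrated stress (0.00897), mesenchyme (0.0387) and leukocyte (0.0387) lists that the unblocked fit does not call.

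Of the 10 lists called by camera, which compares a list with all other genes, 0 were called with an estimated correlation. For YAP/TAZ targets and WNT signalling the estimates, 0.0097 and -0.0097, were not above the preset 0.01, so a higher correlation did not end these 2 calls. For YAP/TAZ targets camera's adjusted p went from 1.17e-06 to 0.575 at nearly the same correlation. A call lost with this setting therefore does not by itself show that a list's members move together. For the other 8 the estimates were above the preset, from 0.0504 for stem-state markers to 0.999 for interferon genes, and the cause was not tested. For these 8 the preset may be too low. An estimated correlation rests on 2 residual degrees of freedom and is imprecise. A call lost with it does not show that a list was unchanged. fry, which asks another question, whether a list's genes move one way on balance and not whether they move more than other genes, called 0 of the 10. With an estimated correlation the adjusted p was 0.575 for the Hippo pathway, YAP/TAZ targets, stem-state markers, WNT signalling, matrix and integrins, and histones, 0.742 for mitosis and interferon genes, 0.699 for immediate early genes and 0.751 for ribosomal proteins. With fry it was 0.118 for the Hippo pathway, YAP/TAZ targets, stem-state markers and WNT signalling, 0.479 for mitosis, 0.328 for matrix and integrins, 0.258 for immediate early genes and histones, and 0.552 for interferon genes and ribosomal proteins. The pluripotency and amnion list, 2 genes, was called with a filter of 1 CPM in 2 libraries (0.0254) and on the 8 columns (0.0359). With 1 library left out the number of lists called ran from 12 to 16. Lowest without knockdown library 1, the adjusted p ran from 5.43e-06 to 0.104 for extravillous, 0.000571 to 0.694 for TGF-beta and BMP, 0.0125 to 0.585 for S phase, 0.00278 to 0.694 for p53, 1.24e-05 to 0.193 for mesenchymal transition and 5.42e-06 to 0.0673 for mesenchyme lists. Lowest without knockdown library 3, it ran from 7.26e-118 to 0.0132 for syncytiotrophoblast, 0.00607 to 0.679 for WNT, 1.25e-05 to 0.819 for mitosis, 2.11e-159 to 0.565 for interferon, 2.66e-17 to 0.146 for integrated stress, 1.07e-05 to 0.467 for sterol, 0.00607 to 0.939 for endothelial and 4.42e-15 to 0.819 for ribosomal protein lists. Lowest without control library 1, it ran from 0.0222 to 0.497 for leukocyte and 6.08e-05 to 0.616 for histone lists, the latter not called without knockdown library 1 or 3 (0.616 and 0.0693). Some lists not called in the main fit were called without control library 1 or without control library 3: TGF-beta and BMP (0.0308 and 0.0442), mesenchyme (0.0225 and 0.0164) and integrated stress (0.0166 and 0.0132) lists without either, and mesenchymal transition (0.0276) and leukocyte (0.0222) lists without control library 1. Hippo, YAP/TAZ target, stem-state, matrix and immediate early lists were called without any 1 library. The direction turned without knockdown library 1 for the syncytiotrophoblast (5.6e-16), interferon (0.565) and ribosomal protein (0.819) lists, and without library 3 for the endothelial list (0.00607). Genes changed at least 2-fold in both knockdown libraries at 10 CPM or more, 72 and 78, became 316 and 216 with no minimum CPM, by construction; all of these settings were added after the data were seen.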

Other observations

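Further differences between single genes, some of them members of the lists, were picked after their values were seen. In knockdown library 3, 4 members of the WNT list stood far above the controls: SP5 was at 22.5 CPM against 0.246 and 0.0802 CPM, LGR5 at 4.16 against 0.0308 and 0.294 CPM, NKD1 at 5.02 against 0.338 and 0.348 CPM, and NOTUM at 59.9 against 9.84 and 9.01 CPM. In knockdown library 1 the same 4 genes were at 0.529, 0.529, 0.378 and 12.6 CPM. Other members rose less in library 3, TCF7 by 1.74, AXIN2 by 1.08, RNF43 by 0.54 and ZNRF3 by 0.38 on the log2 scale. Of 39 members 23 were lower there, among them TCF7L1 by -2.85. MSX1, a homeobox gene, was at 128.1 CPM in library 3, 6.27 CPM in library 1 and 7.44 and 6.76 CPM in the controls, and CDX2, an early trophoblast regulator, had 231 counts in library 3 against 7 in library 1 and 7 and 9 in the controls. SERPINE1, TFPI and ADAMTS20 were at 58.8, 0.852 and 0.331 CPM in library 3, against 386.3, 24.3 and 36.8 CPM in control library 1 and 350.3, 132.9 and 90.2 CPM in knockdown library 1. DESeq2 called none of SP5, LGR5, NKD1, NOTUM, MSX1, SERPINE1, TFPI and ADAMTS20 across groups.

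Other genes moved alike in both knockdown libraries. CD74, a member of the macrophage and leukocyte list, was at 11.5 and 11.1 CPM in the controls and at 24.6 and 60.8 CPM in knockdown libraries 1 and 3 (DESeq2 adjusted p = 0.0023), and PSG9 at 42.8 and 40.5 against 152.5 and 100.2 CPM, with reads that PSG copies can share. HMGCS1, an early enzyme of sterol synthesis, was lower by -0.98 and -0.66 (DESeq2 adjusted p = 0.00354), and EGLN3, an oxygen-sensing hydroxylase, by -0.61 and -0.62 (0.00296). BTG2 was lower by -0.97 and -0.68 and TP53I3 higher by 1.03 and 0.75 on the log2 scale, although both are targets of p53 (DESeq2 adjusted p = 0.00214 and 0.00287).

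The tests below were chosen after the results were seen, except the 2 that correct for GC content and transcript length. Interferon-response genes were high as a list in knockdown library 1 and not in library 3, where 6 of 17 members were still above the controls. A GC or length trend as the whole cause is argued against, since the list's median change of 4.19 in library 1 was 4.14 after a loess correction on both. RNA from leukocytes is argued against by PTPRC, TYROBP, FCER1G, HLA-DRA and CD163, which together reached 0.388 CPM in that library. They were at 0.0900 and 0.182 CPM in control libraries 1 and 3 and at 0.0968 CPM in knockdown library 3. The macrophage and leukocyte list, with 4 tested members, was higher by a median of 0.99 in library 1 and of 0.65 in library 3 on the log2 scale. The part played by loss of TAZ cannot be told apart: the median of -0.34 in library 3, where WWTR1 was as low, belongs to the pattern itself and so tests nothing. A candidate explanation that stays open and untested is a response to the hairpin, the vector or a virus in that culture, beside the higher ribosomal RNA share of the same library; IFNL1, IFNL2 and IFNL3 had 34, 24 and 29 counts there, 14, 2 and 0 in library 3, 5, 1 and 1 in control library 1 and 6, 1 and 1 in control library 3, so IFNL1 was not raised in library 1 alone.

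Syncytiotrophoblast markers were high in knockdown library 1 and low in library 3. The median difference between the 2 libraries of 2.64 was 2.31 after the correction for GC content and length, so such a trend is not the whole cause. For LEP, a single change in the share of syncytiotrophoblast RNA is argued against, because LEP was 3.01 log2 units above the controls in library 3, where the list was below them. CRH was above the controls there too, by 3.14, but from 0.123 and 0.0802 CPM, near the floor, and GDF15 by 0.15. For the list as a whole such a change stays open: the difference had an interquartile range of 2.49 log2 units over the 22 markers at or above 10 CPM in the controls, LEP among them, but markers also made by stem-state cells would move less, and that cannot be told apart here. The knockdown cultures may have differed in how far they had drifted toward fusion, and no label gives their passage, density, day or hairpin.

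The control libraries were nearly alike and the knockdown libraries far apart. Depth is argued against: with all libraries thinned to the same total, the chi-square ratio of the knockdown pair was 95.7 times that of the control pair. A knockdown library that is a mislabelled control is argued against by WWTR1, which was 1.51 log2 units or more below the controls in each (-1.51 in library 1). The ratio of 1.32 for the control pair, near that of lanes, is consistent with both control libraries coming from 1 RNA sample or 1 culture. If so, the comparison rests on 1 independent control, and the spread it is tested against comes from the knockdown libraries; whether these carried different hairpins or were different cell populations was not tested.

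The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 2267 genes at an unadjusted p under 0.05, the highest of the others 56, and 1 of the 3 splits gave as many as the real one, which is itself. Each of the other splits puts 1 control and 1 knockdown library on each side. Their spread within a side then includes the difference between control and knockdown. The control libraries were nearly alike, so these splits could hardly give many genes. The contrast therefore does not show a group effect.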
